A study of Mus musculus with 6 samples.

How the data were processed

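RNA was sequenced from C2C12 myotubes, the muscle fibre-like cells that a mouse myoblast line forms after fusion. There were 6 libraries, 3 from cultures given 20 µM sorafenib for 24 h and 3 from control cultures given 0.1% DMSO for the same time. The series describes the replicates as independent experiments. Per the labels' protocols, messenger RNA was enriched by poly(A) selection and made into stranded libraries. RNAs without a poly(A) tail are therefore recovered only in part.

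The deposited table lists 55356 genes, of which 29160 have a value above 0 in any library and 26196 are at 0 in all 6. Its per-library signal values are normalized counts made by the authors with DESeq2, per the file headers and the submitters' processing notes. They are not raw counts: the mean of the 6 columns equals the deposited base mean, within a relative tolerance of 1e-06, for all 55356 genes. The authors also deposited a log2 fold change with its standard error, a Wald score, and a p-value with an adjusted p-value for each gene, which are described here only as theirs. The submitters' processing notes name bcl2fastq, DESeq2 and the build GRCm38.p6, without tool versions. The quantification tool is not given in the sources used here.

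The genome positions in the deposited table do not match GRCm38. Of the 52080 gene identifiers shared with GENCODE M21 (94.1% of those listed), only 1739, or 3.34%, have a start and end within 1 base of the GRCm38 ones. Positions printed in the text are therefore those of GENCODE M21 on GRCm38, matched by gene identifier without its version. The table's own positions were used only to find neighbouring genes.

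Depth was estimated from the low values. In each library 414 to 582 genes share a smallest step, the value of a single read, of 0.913 to 1.19 normalized counts. Dividing the normalized totals by that step gives roughly 65.5 to 80.2 M reads per library. Between 59.4% and 68.5% of low values were whole multiples of the step within 0.02. The other low values were not whole, so whole reads could not be recovered for every gene. No count model was fitted, and the planned count-based alternatives were not run.

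The test was limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust empirical Bayes, on log2(normalized count + 1). This was the branch fixed for a table of normalized values before the data were examined. Genes with at least 10 normalized counts in at least 3 libraries were kept, which left 16645. Group was the only term, p-values were adjusted by Benjamini-Hochberg over all genes tested, and 0.05 was the threshold. A fold change on this scale understates the change of genes with low values. A gene listed at 0 in every library of a group is given as its values, without a fold.

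There were 30 gene lists, also fixed beforehand, of which 29 had at least 3 tested members. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, again with a correlation estimated for each list, and with fry. The rule for named genes, fixed at the same time, took 3 kinds. The first was the 5 largest increases and 5 largest decreases among called genes with a mean of at least 100, separate groups and a symbol that is not a predicted-gene, clone or pseudogene name. The second was the 2 members with the smallest p of each list past camera, the 1 such member of each other list, and the most abundant member of each marker list of another cell type. The third was Wdr5, Ash2l, Kmt2a, Setd1a, Myod1, Myog, Mymk, Myh3, Fbxo32, Trim63 and Gapdh. Of the genes this rule took, 2 are not reported here. Any other gene named in the text was chosen after its values were seen.

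On simulated data with known changes, the limma step, run on 16375 genes for sorafenib against DMSO, recovered 60.3% of genes changed by 0.5 on the log2 scale, 69.6% of those changed by 1 and 95.2% of those changed by 2. Of its 153 calls, 5.2% were false. The simulated genes varied independently, so this check does not cover genes that vary together. It changed 78, 56 and 62 genes at these sizes, far fewer than the 76.6% called in the real data. No error in the scaling of libraries was simulated. Its rates therefore need not hold for the real comparison.

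Alternatives were quantile normalization, no filter on low values, a minimum of 50, pseudocounts of 0.1 and 10, the replicate number as a block, and leaving out each of the 6 libraries in turn. Scaling each library to equal totals was added after the data were seen. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the plots. No per-sample column was left unused.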

Results

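The data are normalized counts of poly(A)-selected RNA from C2C12 myotubes, multinucleate cells that a mouse myoblast line forms in culture. Sorafenib is an inhibitor of several protein kinases that is used against cancer. The single comparison set 3 libraries from cultures exposed to 20 µM sorafenib for 24 h against 3 libraries from cultures in 0.1% DMSO, its solvent. It asks how sorafenib alters gene expression in muscle cells. The series title ties this to muscle wasting and to the SET1/MLL complex, which methylates histone H3 at lysine 4. Normalized totals were 77972419 to 78898086 per DMSO library and 70211431 to 70598400 per sorafenib library. Estimated depth was 65.5 to 80.2 M reads in DMSO and 76.4 to 77.3 M in sorafenib.

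Genes of muscle contraction, myogenic regulation, mitochondrial respiration and sterol synthesis were lower in sorafenib. Genes of the integrated stress response and of protein folding in the endoplasmic reticulum were higher. For the messenger RNAs with a poly(A) tail encoded in mitochondria, a lower yield in the selection cannot be told apart from an effect of sorafenib. Embryonic myosin heavy chain (Myh3) fell from 587479 ± 32663 to 146824 ± 19176 normalized counts (SD, n = 3 each), 4.02-fold. Hsp90b1, a chaperone of the endoplasmic reticulum, rose from 53310.9 ± 1321 to 431744 ± 11743, 8.10-fold. Of 16645 genes tested, 6453 were higher and 6297 lower in sorafenib, together 76.6%. The change was at least 2-fold for 2078 of the higher and 2881 of the lower genes, but for 2602 and 2528 after scaling to equal totals, which turns the balance. In 79.5% of genes the 3 sorafenib libraries lay wholly on one side of the 3 DMSO libraries, against 10% by chance. The first principal component held 86.7% of the variance and separated the groups. Log2 values correlated across genes at 0.991 to 0.993 within a group and at 0.919 to 0.929 between groups. Scaling to equal totals shifted the median log2 change of all genes by 0.155, so small changes are relative to the scaling used. By the authors' deposited table, there were 6213 higher and 6120 lower genes at an adjusted p under 0.05. The calls shared with the limma fit numbered 11885, all in the same direction.

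**Figure D1:**
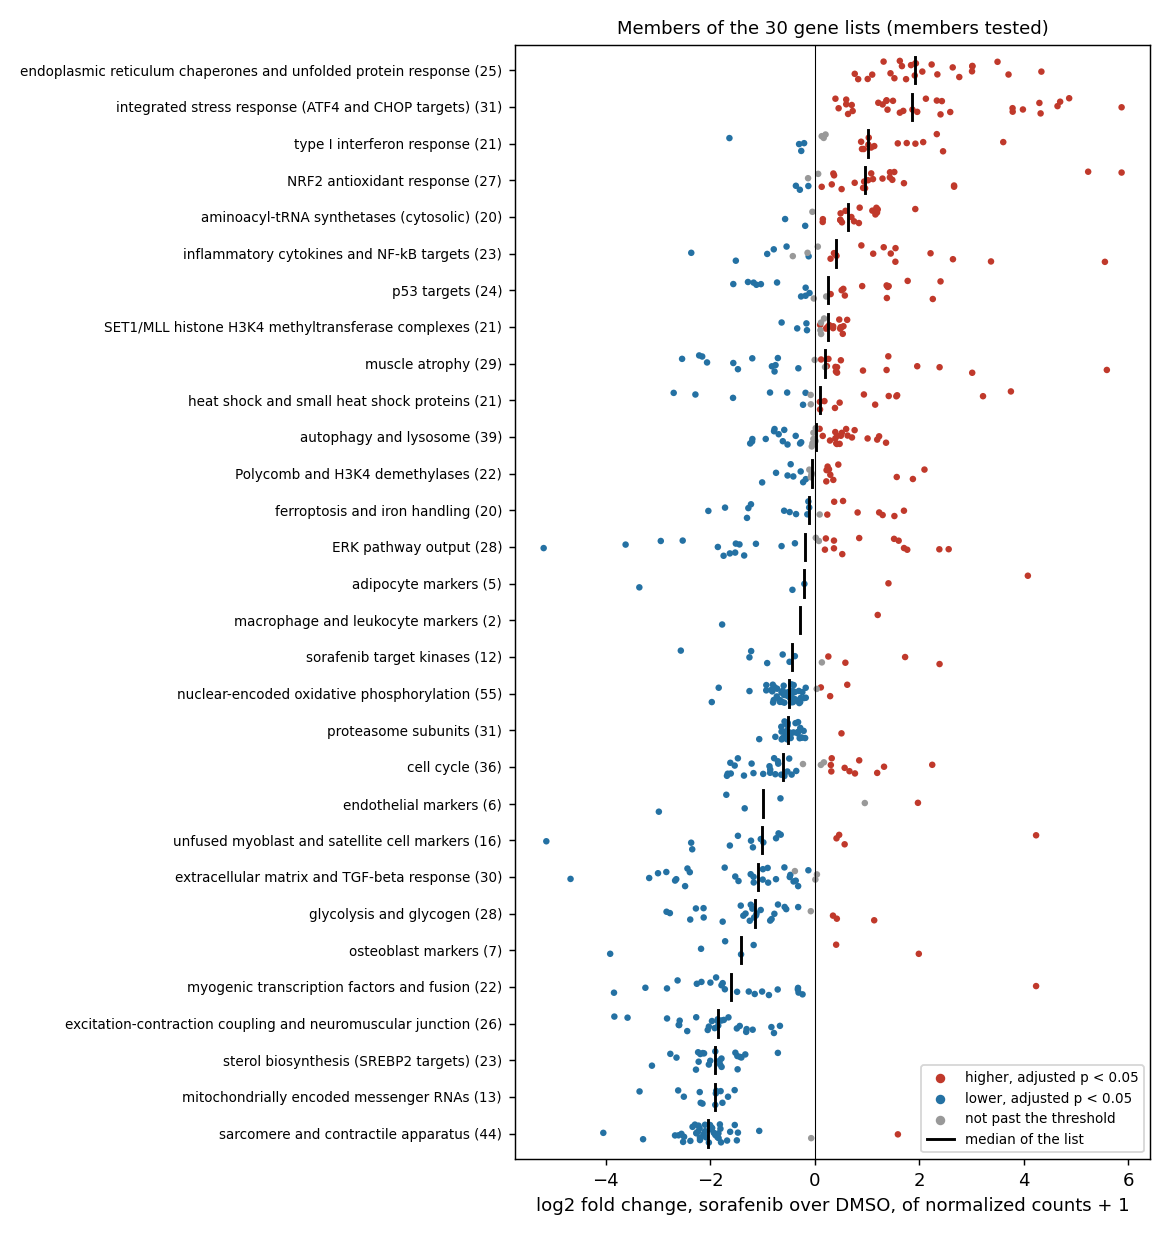
Fitted log2 fold change (sorafenib over DMSO) of each tested member of the 30 gene lists, one point per gene, coloured by limma's call. The vertical bars mark list medians, which run from −2.05 for the sarcomere list to 1.92 for the endoplasmic reticulum chaperones.

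The gene lists need a limit stated beside them. With a preset correlation between genes, limma's camera called 15 of the 29 lists tested, 5 up and 10 down. With an estimated correlation limma's camera called 0, with a lowest adjusted p of 0.32 and 2 lists at an unadjusted p under 0.05. The adjusted p values "with an estimated correlation" given below are therefore all above the threshold. The counts of members below rest on the test of each gene. Adjusted over the list alone, the counts were the same for every list except muscle atrophy (16 higher, 12 lower) and ferroptosis (9 higher, 11 lower). The fry test, which asks whether the members of a list move one way on balance without comparing them with other genes, called 27 lists.

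Genes of the contractile apparatus fell almost throughout. Of 44 members tested, 42 were lower, each at least 2-fold, and the median fell 4.14-fold. Tropomyosin 1 (Tpm1, ENSMUSG00000032366.16, chromosome 9, 67022590 to 67049406 on GRCm38 in GENCODE M21) fell from 107372 ± 1482 to 29991.1 ± 1817 (SD, n = 3 each). Its log2 change was −1.84 ± 0.05 (SE, limma adjusted p = 3.17e-09). Desmin (Des), the intermediate filament of muscle, changed by −1.53 ± 0.04. Tmod4, an actin-capping tropomodulin and the exception, rose from 73.1 ± 13.1 to 220.7 ± 22.1. Xirp2 had a change of −0.07 ± 0.22 that did not pass. Limma's camera gave an adjusted p = 3e-11 for the list, and an adjusted p = 0.38 with an estimated correlation.

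All 26 tested genes of excitation-contraction coupling and the neuromuscular junction were lower, by a median of 3.62-fold. Musk, the receptor kinase that organizes the neuromuscular junction, changed by −1.78 ± 0.05 on the log2 scale. Junctophilin 2 (Jph2), which tethers the sarcoplasmic reticulum to the cell membrane, changed by −1.49 ± 0.04. For this list limma's camera gave an adjusted p = 1.4e-09, and an adjusted p = 0.36 with an estimated correlation.

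Of 22 myogenic transcription factors and fusion genes, 21 were lower and 1 was higher, with a median fall of 3.03-fold. Mef2c, a transcription factor of muscle genes, fell from 57204.8 ± 3505 to 3995.6 ± 301, 14.3-fold. Myod1 changed by −2.83 ± 0.09, Myog (myogenin) by −1.78 ± 0.08 and Mymk, the membrane protein myomaker needed for fusion, by −1.76 ± 0.06. Myf5, a myogenic factor of early muscle precursors, was the exception and rose from 932.5 ± 45.2 to 17590.1 ± 132, 18.9-fold. Myf5 lies on chromosome 10 at 107482908 to 107486134. The list had, in limma's camera, an adjusted p = 2.4e-06 for the list, and an adjusted p = 0.32 with an estimated correlation. Among 16 tested markers of unfused myoblasts and satellite cells, 12 were lower and 4 higher, Myf5 among the latter. Hes1, a Notch target, changed by −2.34 ± 0.05. By limma's camera it had an adjusted p = 0.012 for these markers, and an adjusted p = 0.32 with an estimated correlation.

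**Figure D2:**
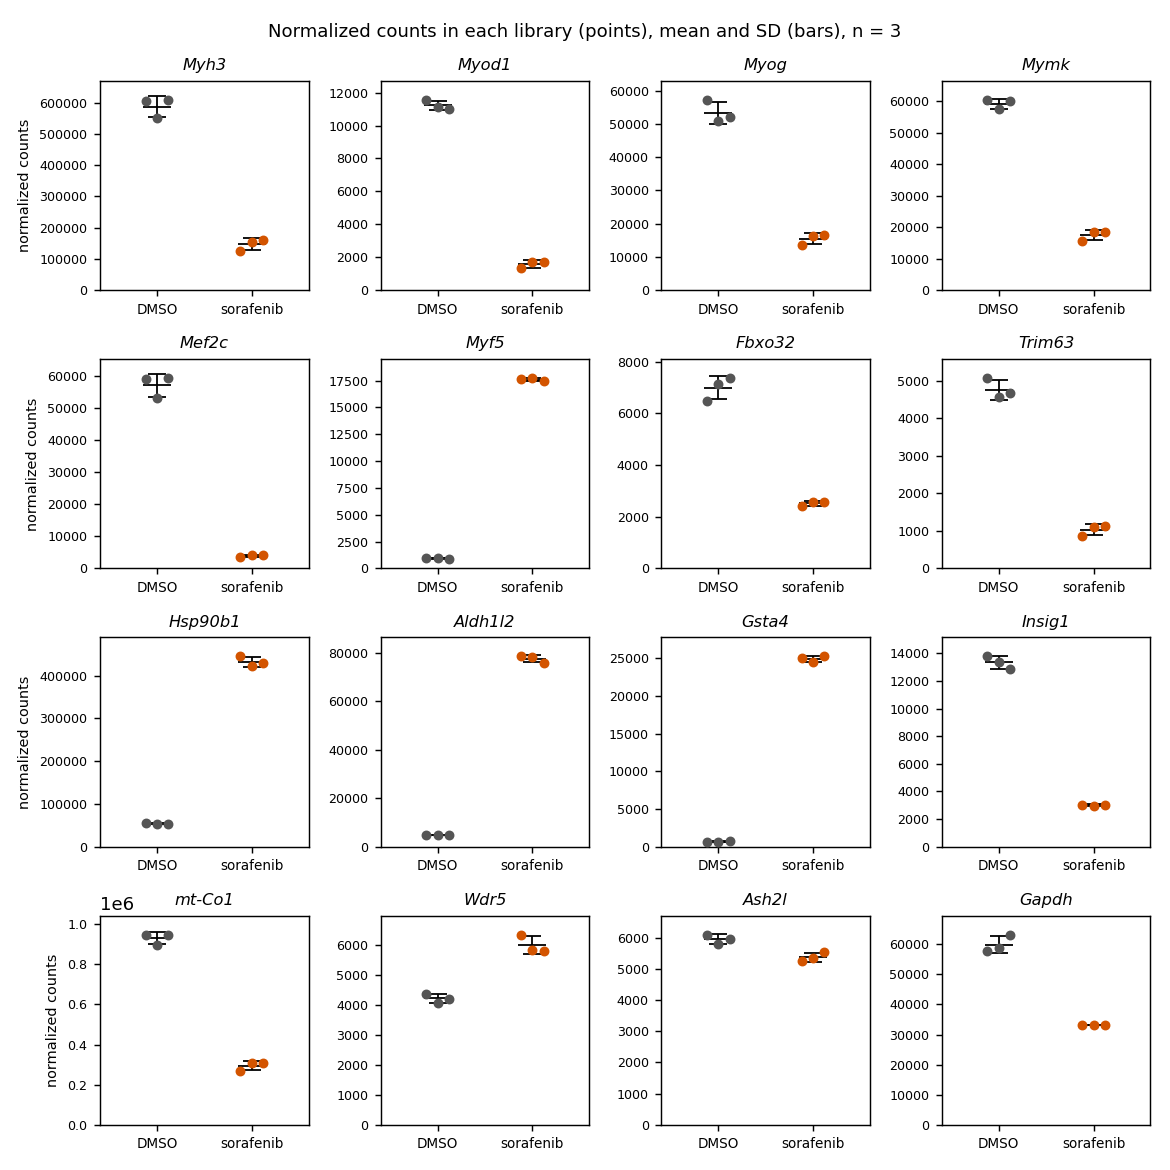
Normalized counts of 16 named genes in each library (points) with the mean and SD (bars, n = 3 per group), on linear axes that start at 0. Myh3 is 587479 in DMSO and 146824 in sorafenib on average, and Myf5 moves the other way, from 932.5 to 17590.1.

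Muscle atrophy genes went both ways, with 15 of 29 tested members higher and 12 lower (limma's camera adjusted p = 0.72). Fbxo32 (atrogin-1) fell from 6984.2 ± 450 to 2520.9 ± 98.3, and Trim63 (MuRF1) from 4767.1 ± 269 to 1035.5 ± 146. Their log2 changes were −1.47 ± 0.05 and −2.21 ± 0.10, and the ubiquitin ligases Trim54, Trim55, Fbxo40 and Nedd4 changed by −2.06, −2.15, −2.54 and −0.75. The ligases Traf6, Itch, Fbxo21 and Fbxo30 had smaller changes of 0.41, 0.26, 0.23 and 0.12, and Fbxo31 did not pass. At a change of at least 2-fold, 6 members were higher and 7 lower. Metallothionein 2 (Mt2), a metal-binding protein, rose 8.08-fold, Mt1 5.24-fold, Cebpb 3.90-fold, Gadd45a 2.66-fold and Eif4ebp1 2.60-fold. Klf15 rose from 5.06 ± 3.71 to 252.3 ± 5.38. The atrophy list shares 6 members with other lists, among them Cebpb and Eif4ebp1 with the targets of the integrated stress response. Of 31 proteasome subunit genes, 30 were lower and 1, Psmd8, was higher at 0.51 ± 0.04. The median fall was 1.43-fold. Psmc3 changed by −1.06 ± 0.04 and Psmd1 by −0.63 ± 0.03. Limma's camera gave an adjusted p = 1.3e-06, and an adjusted p = 0.42 with an estimated correlation. Of 39 autophagy and lysosome genes, 19 were higher and 13 lower (limma's camera adjusted p = 0.72), and Wipi1, which acts in autophagosome formation, changed by −1.20 ± 0.04. The median of this list was 0.02 and camera's direction up, while fry's direction was down.

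Members of the SET1/MLL complexes changed little in size. Of 21 tested, 13 were higher and 4 lower (2 with equal totals), none by 2-fold, and the median log2 change was 0.25. For this list limma's camera gave an adjusted p = 0.06, which does not pass. It passed, by limma's camera, at an adjusted p of 0.047 with the replicate block, 0.018 with no filter on low values, 0.029 with equal totals and 0.046 without sorafenib replicate 3. With an estimated correlation limma's camera gave an adjusted p = 0.32. The core subunit Wdr5 rose from 4219.7 ± 155 to 6006 ± 297, a log2 change of 0.51 ± 0.05. The methyltransferases Kmt2a and Setd1a changed by 0.62 ± 0.07 and 0.49 ± 0.04, and Wdr82, a subunit of the SET1 complexes, by 0.55 ± 0.04. Ash2l changed by −0.15 ± 0.04 (limma adjusted p = 0.00572), and this reversed to 0.01 after scaling to equal totals. Among 22 Polycomb and H3K4 demethylase genes 10 were higher and 8 lower (limma's camera adjusted p = 0.81). Their median was −0.06, against a mean of 0.16, and became 0.10 with equal totals.

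All 31 targets of the integrated stress response, the programme of the transcription factors ATF4 and CHOP, were higher, with a median rise of 3.66-fold. Aldh1l2, a mitochondrial enzyme of folate metabolism, rose from 4895.7 ± 83.3 to 77538.1 ± 1380 (SD, n = 3 each), a log2 change of 3.99 ± 0.03 (limma adjusted p = 1.92e-11). Slc3a2, a subunit of amino acid exchangers, rose 13.8-fold. The list had, in limma's camera, an adjusted p = 3e-11, and an adjusted p = 0.32 with an estimated correlation. Of 20 cytosolic aminoacyl-tRNA synthetase genes, 17 were higher and 2 lower (1 with quantile normalization or equal totals), with a median log2 change of 0.65. Wars changed by 1.93 ± 0.03 and Eprs by 1.16 ± 0.03. By limma's camera it had an adjusted p = 0.00015, and an adjusted p = 0.33 with an estimated correlation.

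All 25 tested chaperone and unfolded protein response genes of the endoplasmic reticulum were higher, by a median of 3.79-fold. Pdia4, a protein disulfide isomerase, rose 8.06-fold, close to Hsp90b1. Limma's camera gave an adjusted p = 3e-11, and an adjusted p = 0.32 with an estimated correlation. Heat shock and small heat shock genes were divided, with 12 of 21 higher and 7 lower (limma's camera adjusted p = 0.33). Hspa1b, an inducible chaperone of the Hsp70 family, rose 9.33-fold, but it has a near-identical copy, Hspa1a, so the split of reads between them is uncertain.

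Of 27 targets of NRF2, a regulator of antioxidant defence, 22 were higher and 3 lower, with a median rise of 1.95-fold. Gsta4, a glutathione transferase, rose from 662.1 ± 43.4 to 24915.6 ± 395, 37.6-fold. Srxn1 (sulfiredoxin) rose 6.35-fold. For this list limma's camera gave an adjusted p = 4.1e-05, and an adjusted p = 0.32 with an estimated correlation. Ferroptosis and iron genes were divided, 8 higher and 11 lower of 20 (limma's camera adjusted p = 0.81). Their median of −0.11 became 0.06 with quantile normalization and 0.04 with equal totals, and fry's direction was up. Sat1, which acetylates polyamines, rose 2.88-fold.

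Glycolytic and glycogen genes were lower in 24 of 28 cases and higher in 3, with a median fall of 2.20-fold. Pyruvate kinase (Pkm) changed by −1.19 ± 0.03 and Slc16a3, a lactate transporter, by −2.83 ± 0.08. Gapdh, often used as a reference gene, fell from 59903.4 ± 2905 to 33175.3 ± 86.1, 1.80-fold. The list had, in limma's camera, an adjusted p = 5.5e-06, and an adjusted p = 0.32 with an estimated correlation. Of 55 nuclear genes of oxidative phosphorylation, 51 were lower and 3 higher, with a median log2 change of −0.49. Atp5a1, of the ATP synthase, changed by −0.81 ± 0.03. By limma's camera these genes had an adjusted p = 3.4e-09, and an adjusted p = 0.38 with an estimated correlation.

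All 13 messenger RNAs encoded in mitochondria were lower, by a median of 3.74-fold. Mt-Co1 fell from 930887 ± 28894 to 295411 ± 22436 and mt-Nd1 from 209668 ± 11653 to 34308.8 ± 2258, 3.16-fold and 6.11-fold. Limma's camera gave an adjusted p = 6.9e-06 for the list, and an adjusted p = 0.36 with an estimated correlation. RNA of the mitochondrial genome made up 3.76% to 4.10% of normalized counts in DMSO and 1.75% to 1.97% in sorafenib. Without its ribosomal RNAs the share was 3.51% to 3.83% in DMSO and 1.00% to 1.22% in sorafenib. The share of the ribosomal RNAs alone was 0.25% to 0.27% in DMSO and 0.74% to 0.76% in sorafenib. Both mitochondrial ribosomal RNAs were higher, mt-Rnr1 by 2.59 ± 0.04 and mt-Rnr2 by 0.90 ± 0.04 on the log2 scale. These were singled out after their values were seen, and poly(A) selection recovers such RNAs only in part.

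**Figure D3:**
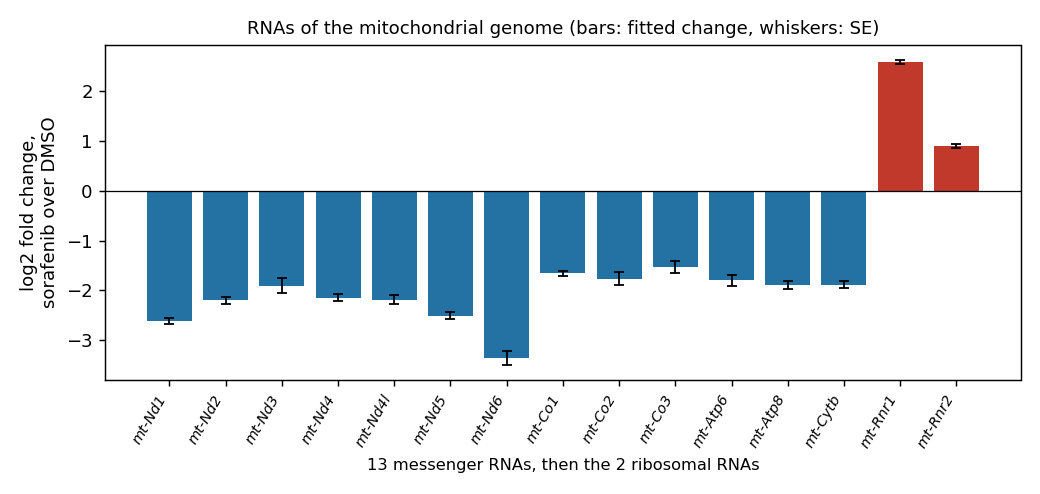
Fitted log2 fold change (sorafenib over DMSO) of the RNAs of the mitochondrial genome, with limma's SE as whiskers. All 13 messenger RNAs lie below 0, from −3.35 for mt-Nd6 to −1.53 for mt-Co3, and both ribosomal RNAs lie above it.

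All 23 sterol synthesis genes, targets of SREBP2, were lower, by a median of 3.74-fold. Acat2 fell from 7615.9 ± 101 to 1755.4 ± 12.8 and Insig1, which restrains SREBP processing, from 13349.2 ± 441 to 3023.1 ± 43.6. For this list limma's camera gave an adjusted p = 2e-10, and an adjusted p = 0.32 with an estimated correlation. Of 30 tested genes of the extracellular matrix and the response to TGF-beta, 27 were lower and 0 higher, with a median fall of 2.11-fold. The other 3 did not pass, but 3 genes were higher with quantile normalization and 2 with equal totals. Acta2 (smooth muscle actin) fell 7.99-fold and Tgfb1 2.87-fold. The list had, in limma's camera, an adjusted p = 3.9e-07, and an adjusted p = 0.32 with an estimated correlation.

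Transcripts read as output of the ERK pathway went both ways, 12 higher and 14 lower of 28 (limma's camera adjusted p = 0.47). Myc rose 5.23-fold. Of 12 tested kinases that sorafenib targets, 4 were higher and 7 lower (limma's camera adjusted p = 0.47), and Ddr2, a collagen receptor, rose 5.24-fold. Targets of p53 were divided, 12 higher and 10 lower of 24 (limma's camera adjusted p = 0.47), and Sesn2, which is also on the stress response list, rose 5.31-fold. Of 36 cell cycle genes 23 were lower and 10 higher (limma's camera adjusted p = 0.11, against 0.027 without DMSO replicate 3, 0.037 with no filter on low values, 0.048 with equal totals and 0.8 with an estimated correlation), and Cdt1, which licenses replication origins, rose 4.76-fold.

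Of 21 tested type I interferon response genes, 14 were higher and 4 lower (2 with equal totals). H2-D1 and B2m, parts of the class I histocompatibility complex, rose 1.87-fold and 1.85-fold. By limma's camera it had an adjusted p = 0.0092, and an adjusted p = 0.32 with an estimated correlation. Inflammatory genes were higher in 14 and lower in 6 of 23 cases (limma's camera adjusted p = 0.099, against 0.031 with no filter on low values), and Csf1, a macrophage growth factor, rose 2.92-fold. Of the macrophage and leukocyte markers 2 of 12 reached the minimum. The most abundant, Cd14, rose from 277.9 ± 15.4 to 643 ± 40.3, and the other, Itgam, fell from 61 ± 8.6 to 17.1 ± 1.9. With no filter on low values 2 of these markers were lower. Of 6 tested endothelial markers 4 were lower and 1 higher (limma's camera adjusted p = 0.34). With quantile normalization, no filter, the replicate block or without DMSO replicate 2 there were 2 higher, and with a minimum of 50 there were 2 lower and 0 higher. The most abundant, Vwf, changed by −0.65 ± 0.20, which did not pass with quantile normalization, without DMSO replicate 3 or without sorafenib replicate 3. The adipocyte markers had 5 tested members, 2 higher and 3 lower (limma's camera adjusted p = 0.91), with a median of −0.20, a mean of 0.30 and Cd36 lower 10.2-fold. Only 1 was lower with quantile normalization, equal totals, no filter or the replicate block, and without DMSO replicate 3 or any 1 of the sorafenib libraries. Of 7 tested osteoblast markers 5 were lower and 2 higher (limma's camera adjusted p = 0.2), with Spp1 lower 2.65-fold. Without DMSO replicate 1, without sorafenib replicate 1 or with the replicate block 1 was higher, and with a minimum of 50 there were 2 lower.

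The largest increases were of genes low or listed at 0 in DMSO. Car6, a secreted carbonic anhydrase (chromosome 4, 150187015 to 150201332), rose from 39.4 ± 5.21 to 16136 ± 601, a log2 change of 8.65 ± 0.09 (limma adjusted p = 1.23e-10). Elmo1, which acts in cell motility, rose from 13.9 ± 0.316 to 4686.1 ± 476 and Avil, an actin-binding protein, 215-fold. H2-M10.1 was listed at 0 in each DMSO library and at 293.8, 250.6 and 223.1 in the sorafenib libraries. Snord3b3 was listed at 0 in each DMSO library and at 451.4, 540.0 and 162.3 in sorafenib, but it has near-identical copies, so the value of a single copy is uncertain. The largest decreases were of Lgr5, a receptor of R-spondins, from 698.8 ± 193 to 5.14 ± 1.75, and of Eif1ad7, from 238.7 ± 88.3 to 2.45 ± 2.12. Eif1ad7 changed by −6.34 ± 0.63 on the log2 scale, but by −5.60 without sorafenib replicate 3, where it is listed at 0, which is less than the change of Lincmd1. The muscle long non-coding RNA Lincmd1 fell from 10655.2 ± 575 to 183.3 ± 42.2, 58.7-fold. Rnase6 fell from 448.7 ± 100 to 7.25 ± 1.89 and Prelp, a matrix proteoglycan, 37.2-fold. With a pseudocount of 10 the changes of genes this low shrank, for Lgr5 from −6.83 to −5.52, for Eif1ad7 to −4.26 (−7.65 with a pseudocount of 0.1), for Rnase6 from −5.77 to −4.71 and for Elmo1 from 8.29 to 7.61. Among named genes the fits of H2-M10.1 and Snord3b3, given here without a fold, depended most on the pseudocount.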

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

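Every alternative was chosen before the data were examined except the scaling to equal totals, which was added after they were seen. The 4 counts of genes stayed within 1.5 times under all 13 alternatives. Without each library in turn, 6136 to 6345 genes were higher and 6009 to 6172 lower. With an estimated correlation camera called 0 lists in place of 15. The estimates reached 0.755, for the sarcomere list. The markers of unfused myoblasts lost their call too, at an estimate of −0.022, which is below the preset 0.01. A higher correlation within a list was therefore not needed for the loss of its call, and the cause was not tested. The other alternatives gave 15 to 18 lists. Equal totals gave 7734 higher and 5285 lower genes, with 59.4% of calls higher in place of 50.6%. At 2-fold it gave 2602 higher and 2528 lower genes, so that the excess of lower genes turned. Among 65 named genes, Ash2l reversed, to 0.008 with equal totals, and the cause is the shift of 0.155 that this scaling adds. Vwf lost its call with quantile normalization, without DMSO replicate 3 and without sorafenib replicate 3, at −0.475, −0.493 and −0.495. Of other called list members, Fth1, Ireb2, Aco1, Eda2r, Sparc and Nfkb1 changed sign under a scaling. Counts of list members moved by over 1.5 times in 10 cases for higher and 15 for lower members. The lists of ferroptosis and adipocyte markers, which no setting called, changed camera's direction, the cause of which was not tested: the former with quantile normalization (adjusted p = 0.92, limma's camera) and the latter without DMSO replicate 1 (adjusted p = 0.97, limma's camera, and 0.87 to 0.97 without each library in turn). The lists of SET1/MLL complexes, cell cycle and inflammation gained a call in 8 cases under limma's camera, for SET1/MLL at an adjusted p of 0.018 to 0.047 without a filter, with equal totals, with the replicate block and without sorafenib replicate 3.

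The replicate numbers were not taken to pair the libraries. Deviations of same-numbered libraries correlated at 0.077, 0.045 and 0.022, though 5 of 6 libraries correlated best with their own number. The library numbers in the column headers alternate between DMSO and sorafenib in replicate order, so pairing is not excluded. With a replicate block 6404 genes were higher, 6231 lower and 16 lists called. The planned count-based alternatives were not run, because whole reads could not be recovered for every gene. Depth limits genes near the minimum of 10, where a normalized count is worth about 1 read.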

Other observations

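The families, the tests of marker RNA, of mt-Nd6 and of the mitochondrial ribosomal RNAs, and the comparison of histone genes with the small RNAs were chosen only after the results were seen. Gene families were then grouped by symbol, 36 in all, and adjusted together. Limma's camera called 16 of the 36 families, 9 up and 7 down, with the preset correlation, and 0 with an estimated one, where the lowest adjusted p was 0.41 and 3 families had an unadjusted p under 0.05. The counts that follow rest on the test of each gene. Most members were higher in N-glycosylation (17 of 18, 0 lower), the signal recognition particle and translocon (19 of 22, 3 lower) and COPI, COPII and Tmed vesicle proteins (27 of 31, 2 lower). Of 76 cytosolic ribosomal protein genes 67 were higher and 1 lower, with a small median log2 change of 0.39. Of 18 small nucleolar RNA host genes 14 were higher and 1 lower, Snhg12 by 4.01 ± 0.06 (SE). Of 371 zinc finger genes of the Zfp series 234 were higher and 53 lower. Integrins (18 of 25, 3 higher) and collagens (25 of 35, 8 higher) were mostly lower. These medians kept their sign with quantile normalization and equal totals.

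The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. For the genes, 1 split gave as many as the real one, itself: 6453 higher and 6297 lower, 2078 and 2881 by 2-fold, against at most 2 in any other. For the gene lists, 5 of the 10 splits gave as many as the real one, with 15 lists for the real split and 16 for the highest other. Each other split sets 2 libraries of one group and 1 of the other against the reverse, so it still holds part of the difference between the groups and is no reference without treatment.

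A set of 242 genes under 50 normalized counts in DMSO rose over 8-fold. As the source of the whole set, RNA from macrophages or endothelial cells is argued against. Of the 22 markers 2 were called higher, with an upper limit of 29.2%, which treats the markers as independent. Only 8 of them were tested. The 14 others, counted as not higher, stayed at means of 8.7 or less in sorafenib, where the 242 genes had a median of 93.2. The most abundant of the markers in sorafenib were Cd14 at 643 ± 40.3 and Vwf at 68.6 ± 12.8. Genes known from leukocytes are among the 242, such as Itgb2 (49.7 to 619) and Cd68 (45.5 to 386). The leukocyte markers Ptprc and Csf1r stayed at 0.6 and 4.1 in sorafenib. For 101 of the 242 genes a tested same-strand gene ended within 50 kb upstream. Transcription running on from it may contribute there and cannot be told apart from other sources. The rest of the 242 had no such gene. This does not decide against running on for them, because the search stopped at 50 kb. Overlapping genes and genes below the minimum were not considered. The nearest same-strand upstream gene within 50 kb was higher for 56 of 101 and the downstream one for 42 of 95, a difference of 11.2 percentage points (95% interval −2.7 to 25.2, Fisher's exact p = 0.15). That is 55.4% and 44.2%, against 34.4% and 31.0% beside 242 genes drawn from those under 50 in DMSO that were not called higher. The shares were above this single draw on both sides, which was not tested. Of all 16645 genes tested, 6453 were higher. An effect of sorafenib on these genes stays open.

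The 13 mitochondrial messenger RNAs fell. Scaling of the libraries as the whole cause is argued against, since the higher of the medians under quantile normalization and equal totals was −1.72, with an SD of 0.58 between members. A lower yield of tailed mitochondrial RNAs in the poly(A) selection would spare mt-Nd6, which has no tail, and the 2 mitochondrial ribosomal RNAs. It is argued against for mt-Nd6, whose log2 change minus the median of the 12 others was −1.45. The ribosomal RNAs go with it in part: the lower of the pair lay 2.80 above that median. But both were higher, by 2.59 for mt-Rnr1 and 0.90 for mt-Rnr2. Sparing them would leave them unchanged, so a lower yield of tailed RNAs alone would not give this rise. For the 12 tailed RNAs a lower yield therefore cannot be told apart from an effect of sorafenib, because the untailed RNAs disagree. The written bound rested on mt-Nd6 alone and would exclude it. It was set aside for that reason.

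Some short RNAs without a poly(A) tail rose with sorafenib, Rn7sk by 5.14 ± 0.16 (SE) on the log2 scale and Snora73b by 1.82 ± 0.16. Sharing of reads between copies is argued against for Snord3, since the sum over its copies rose from 27 ± 4 to 1205.9 ± 174 (SD, n = 3 each), 44.6-fold. Weaker poly(A) selection was to be excluded if the other tailless RNAs had a median under 1 with its upper bound under 1, and that bound was met: the median was 0.11 and the interval −0.52 to 0.84. The bound rests on the histone genes, which are 40 of the 46 RNAs, 12 higher and 14 lower. Their median of −0.03 (SD 1.34) lies below the 4.44 (SD 2.23) of Rn7sk and the 8 small nucleolar and Cajal body RNAs. That 4.44 is the change of Snord3a, and other Snord3 copies, whose single values are uncertain, are among these RNAs. Cell cycle genes had a median of −0.61, which sets no limit on a fall of histone RNAs that could hide a rise. The 6 others, which include both mitochondrial ribosomal RNAs, go with weaker selection, with a median of 3.05. Of these 6, 4 were called higher, and Rn7s1 and Rn7s2 did not pass (limma adjusted p = 0.48 and 0.21). Outside this set the long RNAs Neat1 and Malat1 changed by −2.07 ± 0.10 and −0.05 ± 0.12. Whether some histone RNAs carry tails here was not tested, so the bound does not decide against weaker selection. An effect of sorafenib on these RNAs stays open.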
